A study of Mus musculus with 6 samples.

How the data were processed

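Ventricular mRNA of mice was compared between postnatal day 1 (P1) and postnatal day 14 (P14), with 3 libraries per age. Per the labels, each library was made from poly(A)-selected RNA of 3 pooled hearts, 9 hearts per age, so replicates are separate pools of animals. Libraries were sequenced for 36 cycles on an Illumina Genome Analyzer IIx. The authors deposited a table of whole-number read counts per gene for all 6 libraries, named by Ensembl identifier and symbol, and no normalisation is visible in it because the library totals differ. Per the submitters' processing notes, the genome build was GRCm38 (mm10) and the tools included bedtools and edgeR 3.2.4, with no role stated for either. The aligner, the program that counted reads, its use of strand and the annotation are not given in the sources used here. The table holds 14495 genes, and the smallest total of a gene over the 6 libraries is 60, a mean of 10 per library, so genes with lower counts are not analysed here. All 6 columns of counts were used. Each column was tied to its sample by the age and replicate number in its name. The labels give no batch or date; the column names also carry a shared prefix and a different number per library, alternating between ages, whose meaning is not given in the sources used here.

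Total counts were 17353933, 13406479 and 5916557 at P1 and 15725993, 9104230 and 9295536 at P14. The shallowest library, P1 replicate 3, held 5916557 counts, and values of genes near 1 CPM rest on few reads in every library. Standard errors cover the spread between these pools. Positions, transcript GC content and length came from GENCODE M21, an annotation of GRCm38, in which 14316 of the gene identifiers (98.8%) were found and 179 were not. Correlations of libraries and chi-square statistics of each pair found no duplicated library: the statistic per degree of freedom was 12.2 for the closest pair, P14 replicates 2 and 3.

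Analyses were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept with filterByExpr at a minimum count of 10, which left 14301 tested genes and removed 194. Libraries were scaled with the trimmed mean of M-values (TMM), and P14 was compared with P1 in edgeR's robust quasi-likelihood F-test with age as the only term. P-values were adjusted by the Benjamini-Hochberg method, and genes under 0.05 were called. Tests were two-sided. The common biological coefficient of variation was 23.0%. Standard errors of log2 fold changes were derived as the fitted coefficient divided by the square root of F. CPM are TMM-scaled, and fold values are from the fitted log2 fold change.

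In all, 39 gene lists (25 of pathways or functions and 14 of cell type markers) were fixed, and members were counted as risen or fallen both among all genes tested and with p-values adjusted over the list alone. The 36 lists with at least 5 tested members were tested against other genes with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether the members of a list move on balance in 1 direction. The main test, the lists, the settings varied first and the rule for naming genes were chosen before the data were examined. By that rule the text names 11 genes whatever their result, up to 3 members per list with the largest change among called members of at least 10 CPM (or among all called members where none reached 10), at most 1 further member per list against its main direction, and the 5 largest rises and falls among called genes of at least 10 CPM with no overlap between ages. These made 130 named genes; 1 of them, and 1 gene outside that rule, are not reported here. Exceptions, named after their values were seen, are the interferon-inducible, antigen presentation and tubulin genes, Slc2a4, Lars2, Gm15564, the mitochondrial genes with few unique windows, and members listed only to show a count of 5 or fewer.

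The settings varied first were DESeq2 size factors, library totals alone and upper quartile scaling, leaving out mitochondrial genes and the 10 most abundant genes, no filter and a stricter filter (over 5 CPM in 3 libraries), DESeq2, edgeR's exact test, voom, the replicate number as a block, an adjusted p under 0.01, a fold change above 1.5 (glmTreat), and leaving out each library. Added after the data were seen were a correction of each library for transcript GC content and length (a spline with 4 degrees of freedom), the same with the replicate block, leaving out the mitochondrial rRNAs with Lars2 and Gm15564, and leaving out P1 replicate 2 together with the GC correction. The labels number replicates 1 to 3 at each age without stating that a number is shared. Deviations from the group means correlated at 0.295, 0.112 and 0.103 between libraries with the same number, and at −0.214 to 0.09 between others. By a rule that counts numbers as pairing when every correlation exceeds 0.1, the replicate numbers pair the libraries, which for replicates 2 and 3 rests on values just past that bound. The results given are from the test with age as the only term, and the fit with the replicate number as a block is an alternative to it.

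The test was checked on simulated counts for the comparison of P14 with P1, drawn from the means and library sizes of the real data, with 14127 genes tested. Of 50 genes changed 1.5-fold 12% were recovered, of 50 changed 2-fold 30%, of 50 changed 4-fold 96% and of 50 changed 8-fold 100%. Of 129 calls 9 (6.98%) were unchanged genes. A list with raised members was called by camera (adjusted p = 1.23e-08), and 0 of 20 unchanged lists were called. Genes were drawn independently there, so this cannot show how camera with a preset correlation does on lists of correlated genes. In the real data the cell cycle list had an estimated correlation of 0.327. Far fewer genes changed in the simulation than were called in the real data, which makes its adjusted threshold stricter, so these shares hold for the simulation alone. A gene that did not pass is not shown to be unchanged. Figures were drawn with matplotlib 3.10.9.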

Results

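Messenger RNA was measured in the ventricles of male C57BL/6 mice at postnatal day 1 (P1) and postnatal day 14 (P14). Each age had 3 libraries, and each library came from a separate pool of 3 hearts, so that 9 hearts stood behind each age. The tissue protocol describes whole ventricles with the septum and without the atria, while the tissue field of the same labels names the left ventricle, and both descriptions are given here because they differ. The values are read counts for 14495 genes. Total counts at P1 were 17353933, 13406479 and 5916557 in replicates 1 to 3, and at P14 they were 15725993, 9104230 and 9295536. Between 14419 and 14486 of the genes had at least 1 count in each library.

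The comparison asks which transcripts of the ventricle differ between P1 and P14, in a series whose title names the cardiac methylome over the same period. At P14 transcripts of cell division were lower, the fetal forms of troponin I and myosin heavy chain were lower and the adult forms higher, and many transcripts of fatty acid oxidation and the respiratory chain were higher. Of 43 cell cycle and mitosis genes 41 fell, with a median log2 fold change of −3.39, and 30 of 31 DNA replication genes fell. Fetal troponin Tnni1 fell 140.2-fold and the slow myosin heavy chain Myh7 fell 19.1-fold, while the adult isoforms Tnni3 and Myh6 rose 4.19-fold and 3.57-fold (n = 3 libraries per age). Of 50 nuclear genes of the respiratory chain 39 rose, and of 32 genes of fatty acid oxidation 23 rose. Of 27 imprinted and growth-control genes 21 fell, 14 of 16 macrophage markers rose, and 6 of 7 granulocyte markers fell.

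Rose and fell are used for genes higher or lower at P14 with an adjusted p under 0.05 in edgeR's quasi-likelihood test. Of 14301 genes tested, 3115 rose and 3149 fell, together 43.8% of the genes, and 2035 and 1932 of these changed at least 2-fold. The 3 P1 values did not overlap the 3 P14 values in 54.85% of the tested genes, where chance gives 10%. When libraries were scaled by their totals alone, 1620 genes rose and 5592 fell, and the median log2 fold change of all genes moved from −0.01 to −0.47. The share of rises among the called genes was 49.7% with the trimmed mean of M-values (TMM) scaling used here and 22.5% with totals alone, so directions are relative to the TMM scaling, which assumes that most genes do not change. With totals alone the edgeR calls of 16 named genes ended (Apobec2, Cdkn1a, Cpt1b, Cryab, Gli1, Ier3, mt-Cytb, Mybpc2, Oxct1, Pccb, Snrpn, Sucla2, Tagln, Tnni2, Vwf and Zbtb38), as did the camera calls of the Wnt, histone, circadian, endothelial and fibroblast lists. Such a scaling moves all genes alike, so the list medians that turn sign with it follow that shift: over the median of all genes, those of the ketone, antioxidant, glycolysis, transcription factor, extracellular matrix and fibroblast lists lay at 0.346, 0.323, 0.132, 0.055, 0.048 and 0.441 with TMM and at 0.356, 0.335, 0.138, 0.043, 0.044 and 0.446 with totals alone. Counts within lists moved with it: with totals alone 3 endothelial markers rose and 5 fell, 2 mitochondrially encoded transcripts rose and 3 fell, 0 skeletal muscle markers rose and 2 fell, 2 genes of the tricarboxylic acid cycle rose and 1 fell, 25 nuclear genes of the respiratory chain rose and 3 fell, 16 genes of fatty acid oxidation rose and 2 fell, 7 mature contractile genes rose and 1 fell, 12 channel genes rose and 9 fell, and 5 cardiomyocyte markers rose and 0 fell.

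**Figure D1:**
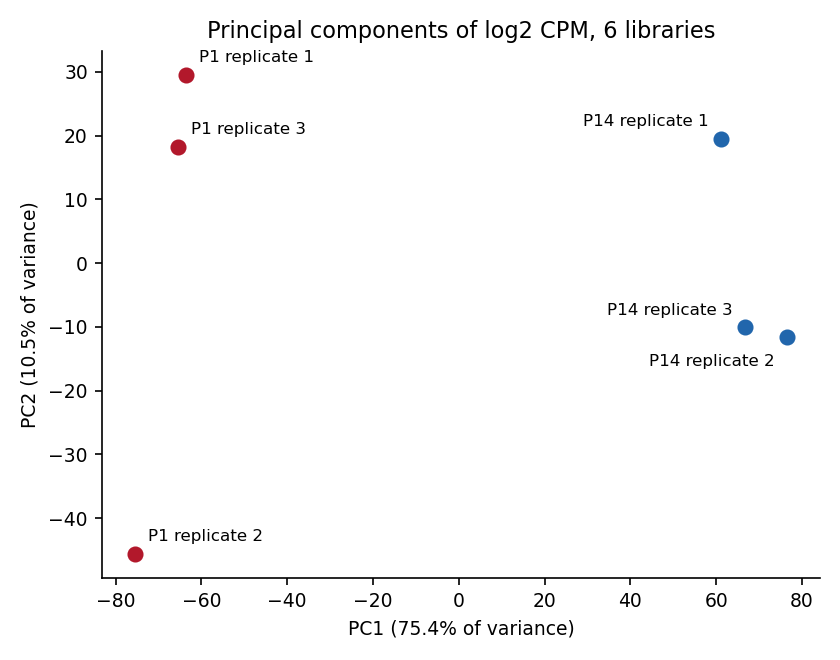
Scores of the 6 libraries on the first and second principal components of log2 CPM, with red points for P1 and blue points for P14. The first component, with 75.4% of the variance, separates the ages, and the second, with 10.5%, places P1 replicate 2 at −45.6 and P1 replicates 1 and 3 at 29.5 and 18.3.

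**Figure D2:**
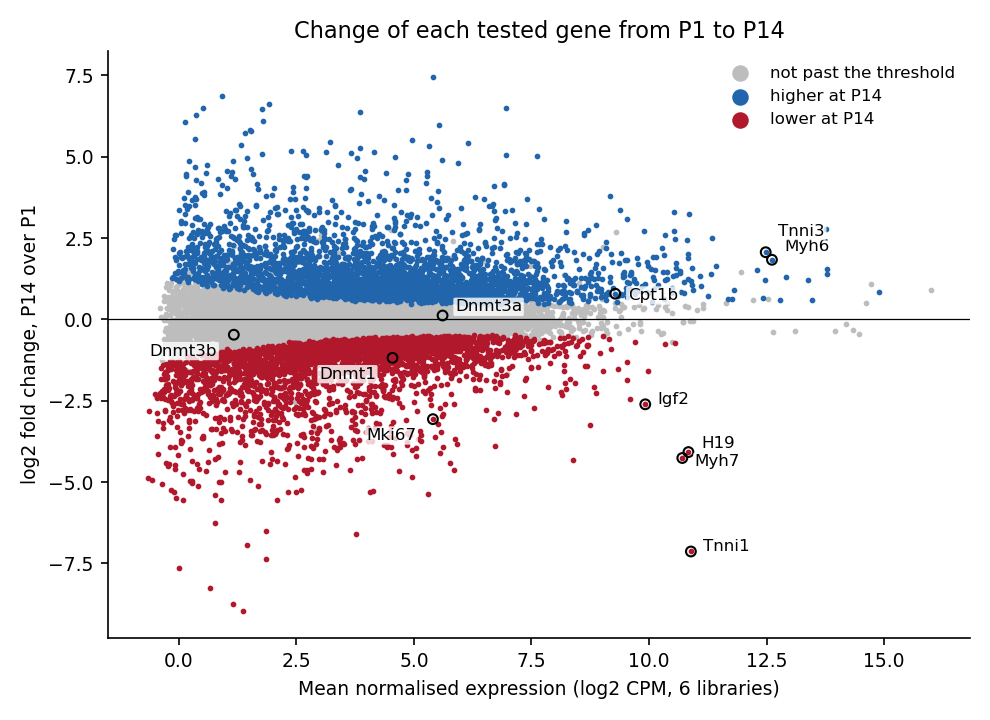
Each point is a tested gene, with mean normalised expression over the 6 libraries on the x axis (log2 CPM) and the log2 fold change of P14 over P1 on the y axis. Blue genes (3115) were higher and red genes (3149) lower at P14 past the threshold, and the 11 circled genes are those reported whatever their result.

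Genes chosen in advance as markers of the postnatal period are given with their position in GRCm38 (GENCODE M21) and with CPM as mean ± SD over 3 libraries per age. Tnni1, the fetal slow skeletal troponin I (ENSMUSG00000026418; chromosome 1, 135779434 to 135810989), fell from 3769.7 ± 1399 to 26.7 ± 13.4 CPM, a log2 fold change of −7.13 ± 0.53 (SE; edgeR adjusted p = 6.31e-06). Tnni3, the adult cardiac troponin I (ENSMUSG00000035458; chromosome 7, 4518305 to 4524229), rose from 2202 ± 633 to 9234 ± 1559 CPM. Myh7, the myosin heavy chain that dominates in the fetal mouse ventricle (ENSMUSG00000053093; chromosome 14, 54970684 to 54994626), fell from 3179 ± 1165 to 166 ± 45.9 CPM, with a log2 fold change of −4.26 ± 0.33. Myh6, the adult myosin heavy chain next to it (ENSMUSG00000040752; chromosome 14, 54941921 to 54966927), rose from 2744 ± 617 to 9795 ± 2537 CPM, with a log2 fold change of 1.84 ± 0.25. The fetal growth factor Igf2 (ENSMUSG00000048583; chromosome 7, 142650766 to 142666816) fell from 1664 ± 272 to 273 ± 61.1 CPM, and the neighbouring noncoding RNA H19 (ENSMUSG00000000031; chromosome 7, 142575529 to 142578143) fell from 3456 ± 882 to 205 ± 43.8 CPM. Mki67, a marker of proliferating cells (ENSMUSG00000031004; chromosome 7, 135689784 to 135716361), fell from 75.6 ± 15.3 to 9.07 ± 1.75 CPM. Cpt1b, the muscle form of the carnitine palmitoyltransferase that admits fatty acids to mitochondria (ENSMUSG00000078937; chromosome 15, 89416405 to 89425863), rose from 456 ± 39.7 to 789 ± 87.1 CPM (edgeR adjusted p = 0.0048). With totals alone its log2 fold change was 0.35 and the call ended (edgeR adjusted p = 0.253). Among the DNA methyltransferases, the maintenance enzyme Dnmt1 (ENSMUSG00000004099; chromosome 9, 20907209 to 20959888) fell from 32.4 ± 7.75 to 14.3 ± 2.16 CPM. The de novo enzymes did not pass with TMM: Dnmt3a (ENSMUSG00000020661; chromosome 12, 3806007 to 3914443) had 46.6 ± 6.71 CPM at P1 and 51.0 ± 8.19 at P14, with a log2 fold change of 0.12 ± 0.20 (edgeR adjusted p = 0.65) whose sign turned to −0.36 with totals alone. Dnmt3b (ENSMUSG00000027478; chromosome 2, 153649450 to 153687730) lay near the lower limit of detection, with counts of 13 to 69 per library, and had 2.57 ± 0.543 and 1.93 ± 0.424 CPM (edgeR adjusted p = 0.309). With totals alone Dnmt3b passed, with a log2 fold change of −0.95 and an adjusted p that rounds to 0.05. Exons of Myh6, Myh7, Igf2, H19 and Dnmt3a overlap annotated genes on the opposite strand, and those of Tnni3, Igf2, H19 and Cpt1b overlap genes on the same strand. Whether the counting used strand is not given in the sources used here, so reads of overlapping genes may be mixed in these values. The same limit holds for many genes named below. Exons of Phox2a, Tead2, Cbx7 and Ube2c, for example, overlap Inppl1, Cd37, Apobec3 and Tnnc2 on the opposite strand. Those of Snrpn overlap Snurf on the same strand.

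**Figure D3:**
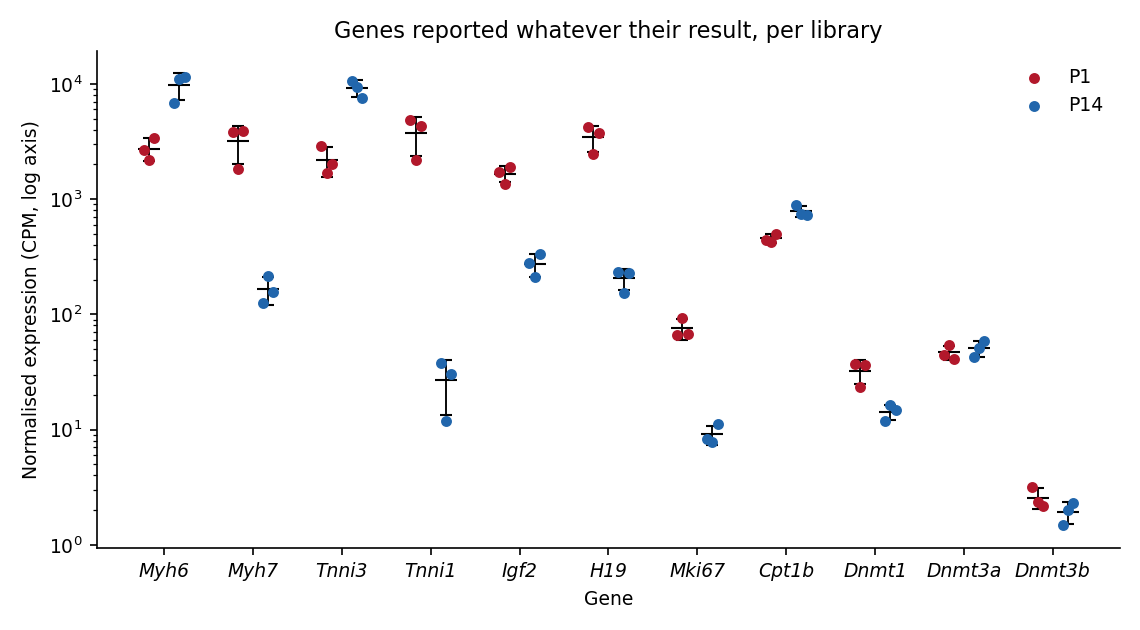
Normalised expression (CPM, log axis) of the 11 genes reported whatever their result, with a point per library (red P1, blue P14) and the mean ± SD of 3 libraries in black. The ages are apart in 9 genes, from Tnni1 (140.2-fold lower at P14) to Cpt1b (1.73-fold higher), and overlap in Dnmt3a and Dnmt3b.

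Cell division genes fell almost without exception. In the cell cycle and mitosis list 41 of 43 tested genes fell and 2 did not pass, among them falls of Nuf2, a kinetochore protein (from 19.4 to 0.771 CPM), Racgap1, which acts in cytokinesis (from 88.5 to 5.03 CPM), and Ube2c, an enzyme of the anaphase-promoting pathway (from 58.7 to 3.46 CPM). In the DNA replication list 30 of 31 fell and 1 did not pass, with the primase subunit Prim1 at a log2 fold change of −3.79 ± 0.30, the ribonucleotide reductase subunit Rrm2 at −3.69 ± 0.29 and the helicase subunit Mcm6 at −2.64 ± 0.27 (SE). The counts were also 41 and 30 adjusted over the list alone. Both lists were lower than other genes in camera with a preset correlation of 0.01 (adjusted p = 2.81e-21 and 8.93e-14), and both had an adjusted p = 0.206 with an estimated correlation. Of 14 cyclin-dependent kinase inhibitors and genes of cell cycle exit, 4 rose, 6 fell and 4 did not pass, with the same counts adjusted over the list alone. Cdkn1a (p21) rose from 76.4 to 153 CPM and the stress-inducible Gadd45a rose from 3.11 to 8.77 CPM, while Cdkn2c (p18) and Meis2 fell with log2 fold changes of −1.49 ± 0.26 and −1.0 ± 0.25. That list as a whole was not called (camera adjusted p = 0.33), and 2 of its members rose without P1 replicate 3.

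Most mature contractile genes rose and most fetal ones fell. Of 18 mature contractile genes 12 rose and 6 did not pass, and 14 rose and 1 fell adjusted over the list alone. The titin-binding Tcap rose from 77.9 ± 37.7 to 1073 ± 80.1 CPM, the largest rise in the list. Of 16 fetal contractile and stress genes 9 fell, 2 rose and 5 did not pass, with the same counts adjusted over the list alone. Nppb, which encodes brain natriuretic peptide, fell from 778 to 162 CPM, and Tagln, a smooth muscle gene, rose from 72.7 to 123 CPM (edgeR adjusted p = 0.0157). The list held 0 rises without P1 replicate 3 or P14 replicate 1 and 1 without P14 replicate 2, and for Tagln the edgeR adjusted p was 0.0585 and 0.0712 in the first 2 cases. Of 36 genes of calcium handling and cardiac ion channels 20 rose, 5 fell and 11 did not pass, and 21 and 5 adjusted over the list alone. Hrc, a calcium-binding protein of the sarcoplasmic reticulum, rose from 155 to 1332 CPM, the potassium channel Kcnk3 from 38.0 to 294 CPM and the pacemaker channel Hcn2 from 2.27 to 26.1 CPM, while Gja5 (connexin 40) fell from 23.2 to 7.34 CPM. Without P14 replicate 2, 14 channel genes rose and 2 fell, 3 fell when P1 replicate 1, P1 replicate 3 or P14 replicate 1 was left out, and 8 fell after correction for GC content and length. By camera the mature list was higher (adjusted p = 1.10e-04), the fetal list lower (0.00436) and the channel list higher (0.00636). None of these held with the correlation estimated from the data: the mature and channel lists had an adjusted p = 0.206 with an estimated correlation and the fetal list an adjusted p = 0.402 with an estimated correlation.

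Many transcripts of oxidative metabolism rose. In fatty acid oxidation 23 of 32 genes rose, 1 fell and 8 did not pass, and 24 rose adjusted over the list alone. Cpt2 rose from 70.2 ± 11.8 to 353 ± 41.0 CPM, the electron transfer flavoprotein subunit Etfb from 455 to 2539.6 CPM and the mitochondrial carrier Ucp3 from 6.72 to 83.7 CPM, while Cpt1a, the liver form of carnitine palmitoyltransferase, fell from 104 ± 22.5 to 57.5 ± 3.27 CPM. Of 50 nuclear genes of the respiratory chain 39 rose, 2 fell and 9 did not pass (41 rose adjusted over the list alone), with Cox8b going from 388 to 2563 CPM, Cox6a2 going from 782 to 4421 CPM and Ndufs7 going from 109 to 729.5 CPM. P1 replicate 2 was the lowest P1 library for Etfb, Cox8b, Cox6a2 and Ndufs7 (Ndufs7 40.7 CPM against 156 and 129), which widens their changes. It was the highest for Cpt2 and Ucp3. Without that library all 130 named genes kept their direction, and none gained or lost a call. Cox8a, the form of subunit 8 found in most tissues, fell from 526 to 303 CPM, a call that ended without P1 replicate 3 (edgeR adjusted p = 0.0996), where 0 genes of the list fell, and 1 fell without P1 replicate 1, P14 replicate 2 or P14 replicate 3. In the tricarboxylic acid cycle 12 of 21 genes rose and 9 did not pass, also 12 adjusted over the list alone, including Ogdh with a log2 fold change of 1.29 ± 0.20, Mdh2 (1.03 ± 0.23) and Sucla2 (1.03 ± 0.24). The 3 lists were higher than other genes in camera (adjusted p = 3.19e-07, 1.30e-09 and 0.00566). In the same order they had an adjusted p = 0.206, 0.247 and 0.439 with an estimated correlation.

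Ketone and carbohydrate genes were mixed. Of 21 genes of ketone body and branched-chain amino acid metabolism 6 rose, 1 fell and 14 did not pass, with the same counts adjusted over the list alone. Oxct1 and Pccb rose with log2 fold changes of 0.85 ± 0.20 and 0.87 ± 0.19, and Bdh1, a ketone body dehydrogenase, fell from 4.63 to 0.2 CPM. Bckdha rose from 39.8 ± 26.8 to 252 ± 30.4 CPM (edgeR adjusted p = 0.018), and its call ended with the replicate number as a block (0.11) and without P1 replicate 3 (0.0507), P14 replicate 2 (0.0546) or P14 replicate 3 (0.0555). That list was not called (camera adjusted p = 0.141), was called without P1 replicate 2 (0.0447), held 3 rises without P1 replicate 1, and had a median log2 fold change of 0.34 and of −0.12 with totals alone, where 1 rose and 5 fell. Of 24 genes of glycolysis and glucose uptake 9 rose, 6 fell and 9 did not pass (9 and 7 adjusted over the list alone). Aldolase C (Aldoc) fell from 26.8 ± 7.20 to 0.249 ± 0.113 CPM, the lactate transporter Slc16a3 from 32.2 to 4.49 CPM and the glucose transporter Slc2a1 from 25.1 to 5.16 CPM. These were named for the size of their change, and more members of the list rose than fell. Another glucose transporter, Slc2a4, rose with a log2 fold change of 1.79. The median of the glycolysis list was 0.12, its mean −0.12 and its camera direction up (adjusted p = 0.726); without P1 replicate 2 the number that fell was 11, the median −0.002 and the camera direction down, and with totals alone the median was −0.33, with 7 rises and 11 falls.

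Of 13 tested transcripts encoded by the mitochondrial genome 3 rose (mt-Nd4, mt-Nd6 and mt-Cytb, the last from 21708 to 38858 CPM) and 10 did not pass, also 3 adjusted over the list alone, and 5 rose with the replicate block. The list was not called (camera adjusted p = 0.278). Exons of mt-Nd6 and mt-Nd5 overlap on opposite strands. In 4 of the 11 mitochondrial coding genes of the table, under 5% of the 36-base windows were unique among annotated transcripts: mt-Co2 (0.0%), mt-Co3 (0.13%), mt-Atp6 (0.46%) and mt-Nd3 (1.92%), whose windows are shared with nuclear copies. These 4 had means of at most 3.88 CPM, while the other 7, with at least 37.4% unique windows, had at least 1528 CPM, so the counts of these 4 genes are uncertain. The 2 mitochondrial ribosomal RNAs took 1.91% to 13.6% of counts at P1 and 3.31% to 15.1% at P14, and neither passed the test.

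Most imprinted and growth-control genes fell: 21 of 27 tested genes fell, 1 rose and 5 did not pass, with the same counts adjusted over the list alone. The paternally expressed Dlk1 fell from 77.2 ± 29.3 to 1.75 ± 1.20 CPM and Mest from 637 ± 19.8 to 32.0 ± 11.3 CPM, beside Igf2 and H19, while Snrpn rose from 29.2 to 59.5 CPM. By camera this list was lower (adjusted p = 1.51e-08), with an adjusted p = 0.206 with an estimated correlation. Of 35 histone-modifying and chromatin genes 14 fell, 4 rose and 17 did not pass, and 15 and 5 adjusted over the list alone. The Polycomb genes Ezh2 and Suz12 fell with log2 fold changes of −1.53 ± 0.21 and −1.46 ± 0.34, the histone methyltransferase Suv39h1 fell with −1.71 ± 0.24, and the Polycomb gene Cbx7 rose with 2.65 ± 0.34. By camera the chromatin list was lower (adjusted p = 0.0396), with an adjusted p = 0.206 with an estimated correlation, and it was not called without P14 replicate 1 (0.0743), where 2 genes rose, as they did without P14 replicate 2. Of 17 genes of the DNA methylation machinery 4 fell, 2 rose and 11 did not pass, with the same counts adjusted over the list alone, and the list was not called (camera adjusted p = 0.33). Its rises were small: Zbtb38, a methyl-CpG-binding protein, rose from 20.2 to 36.7 CPM and Apobec2 from 246 to 381 CPM. Zbtb38 did not pass without P14 replicate 2 or 3 (edgeR adjusted p = 0.0645 and 0.0777), nor Apobec2 without P1 replicate 3 or P14 replicate 1 (0.0858 and 0.106).

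Signalling genes moved in both directions. In the Wnt list 16 of 33 genes fell, 5 rose and 12 did not pass (16 and 6 adjusted over the list alone): the inhibitor Nkd2 fell from 20.7 to 3.97 CPM and the receptor Ror1 from 23.5 to 6.56 CPM, and the receptor Lgr6 rose from 4.32 to 23.3 CPM. By camera it was lower (adjusted p = 0.0396), with an adjusted p = 0.402 with an estimated correlation, it was not called without P14 replicate 1 (0.119), and 10 fell and 3 rose without P14 replicate 2 and 3 rose without P14 replicate 3. In the Notch list 13 of 26 genes rose, 4 fell and 9 did not pass, with the same counts adjusted over the list alone. The target Hes1 rose from 4.93 to 19.4 CPM while the target Hey2 fell from 32.1 to 2.46 CPM, and the ligand-like Dlk1, which the imprinted list also holds, fell. By camera the Notch list was higher (adjusted p = 0.031), with an adjusted p = 0.375 with an estimated correlation. The Notch call ended without P14 replicate 3 (0.0544) and after correction for GC content and length (0.198).

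Of 12 Hedgehog genes 5 fell, 2 rose and 5 did not pass (5 and 3 adjusted over the list alone); Smo, Cdon and Sufu fell with log2 fold changes of −1.34 ± 0.27, −1.02 ± 0.25 and −0.74 ± 0.23, and Gli1, a target of the pathway, rose with 1.33 ± 0.35. The call of Gli1 ended after correction for GC content and length (log2 fold change 0.73, edgeR adjusted p = 0.0799), with the replicate block added (0.70, 0.0867) and with totals alone (0.85, 0.0753). Sufu did not pass without P1 replicate 1, P1 replicate 3, P14 replicate 2 or P14 replicate 3 (edgeR adjusted p from 0.0637 to 0.0772), and the number of falls was 3 without each of the first 3 of these. Of 31 TGF-beta and BMP genes 10 fell, 5 rose and 16 did not pass, with the same counts adjusted over the list alone. Bmp7 fell from 44.9 to 2.47 CPM, and Bmp4 and the BMP target Id1 rose from 2.12 to 11.7 CPM and from 9.08 to 28.7 CPM. Id3 rose with a log2 fold change of 1.71 ± 0.48 (edgeR adjusted p = 0.0207), a call that ended without P1 replicate 3 or any single P14 library (0.052 to 0.0614). Neither the Hedgehog nor the TGF-beta list was called (camera adjusted p = 0.461 and 0.327).

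Of 40 cardiac developmental transcription factors 10 rose, 11 fell and 19 did not pass, with the same counts adjusted over the list alone. Klf9, a target of glucocorticoid and thyroid hormone, rose from 21.5 to 147 CPM and the endothelial factor Sox18 from 11 to 55.0 CPM, and Tead2 fell from 68.3 to 12.6 CPM. Of 45 extracellular matrix genes 15 fell, 8 rose and 22 did not pass, again with the same counts adjusted over the list alone. Periostin (Postn) fell from 475 ± 125 to 94.2 ± 21.3 CPM, the proteoglycan Vcan from 64.3 to 14.4 CPM and Col12a1 from 19.8 to 3.29 CPM, while Col8a1 rose from 1.15 to 12 CPM. Neither list was called (camera adjusted p = 0.909 and 0.461). In both, the median was just above 0 with TMM (0.05 and 0.04), below 0 with totals alone (−0.43 in each) and with upper quartile scaling (−0.02 and −0.03), while the mean (−0.03 and −0.20) and the camera direction (down) were below 0 with TMM. With totals alone 7 transcription factor genes rose and 17 fell, and 6 matrix genes rose and 20 fell. The camera direction of the transcription factor list turned to up without P14 replicate 1, with totals alone and with the stricter filter on low counts.

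Of 27 antioxidant and redox genes 11 rose, 4 fell and 12 did not pass (12 and 5 adjusted over the list alone). The extracellular superoxide dismutase Sod3 rose from 2.45 to 30.3 CPM, Ucp2 from 111 to 676 CPM and Prdx5 from 183 to 792 CPM, and Mgst1 fell from 21.8 to 8.09 CPM. This list had a camera adjusted p = 0.0623, was called without P1 replicate 3 (0.0423), P14 replicate 2 (0.0442) or P14 replicate 3 (0.0342), each with 2 falls, and its median was 0.31 with TMM and −0.14 with totals alone, where 6 rose and 6 fell. Of 19 circadian clock and output genes 8 rose, 2 fell and 9 did not pass (9 and 2 adjusted over the list alone). Dbp, Per3 and Rora rose with log2 fold changes of 1.57 ± 0.26, 1.56 ± 0.26 and 1.35 ± 0.25, and Per1 fell with −1.13 ± 0.24. By camera the circadian list was higher (adjusted p = 0.0313), with an adjusted p = 0.206 with an estimated correlation, and 5 rose without P14 replicate 2. The hour of tissue collection is not given in the sources used here.

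Of 39 cytosolic ribosomal protein genes 10 fell, 0 rose and 29 did not pass, and 9 fell adjusted over the list alone, including Rpl4 (from 961 to 335 CPM) and Rpl5. That list was not called (camera adjusted p = 0.0751), was called lower without P1 replicate 2 (0.00372), and held 2 rises and 7 falls without P1 replicate 1 and 6 falls without P14 replicate 3. After correction for GC content and length 17 of its members fell and it was called lower (0.041). Of 14 immediate early and heat shock genes 5 rose, 1 fell and 8 did not pass, with the same counts adjusted over the list alone. Dusp1 rose from 22.4 ± 0.151 to 82.1 ± 6.94 CPM and Ier3 from 11.1 to 22.1 CPM, and Myc fell from 14.1 to 1.76 CPM. The immediate early list was not called (camera adjusted p = 0.0842) and was called without P1 replicate 1 (0.0478) or P14 replicate 2 (0.0397).

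Markers of the other cell types of the ventricle moved with age. Of 16 macrophage markers 14 rose and 2 did not pass: the complement genes C1qa, C1qb and C1qc rose from 5.42 to 43.1 CPM, from 21.2 to 73.5 CPM and from 9.79 to 51.7 CPM. Of 7 granulocyte markers 6 fell and 1 did not pass, with S100a9 going from 25.7 to 3.48 CPM. Of 9 erythroid markers 8 rose and 1 did not pass, with the transferrin receptor Tfrc, which muscle also expresses, going from 64.8 to 533 CPM. The globin genes Hba-a1 and Hba-a2 rose 4.31-fold and 4.21-fold, but they are near-identical copies whose counts are uncertain, and Hba-a1 did not pass with the replicate block (edgeR adjusted p = 0.0666) or without P1 replicate 1 (0.0554). Without P1 replicate 2 and with the GC correction neither passed (edgeR adjusted p = 0.0733 and 0.0759). These counts were the same adjusted over the list alone. By camera the macrophage list was higher (adjusted p = 5.73e-06), the granulocyte list lower (1.11e-04) and the erythroid list higher (3.12e-04). The macrophage and granulocyte lists had an adjusted p = 0.206 with an estimated correlation and the erythroid list an adjusted p = 0.209 with an estimated correlation.

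Of 14 smooth muscle and pericyte markers 10 rose, 2 fell and 2 did not pass: Vtn rose from 2.73 to 53.9 CPM, Myh11 from 9.13 to 46.5 CPM and Rgs5 from 109 to 420.3 CPM, and Cnn1 fell from 26.4 to 8.19 CPM, with 1 fall in the list without P1 replicate 3, P14 replicate 2 or P14 replicate 3. Of 16 endothelial markers 9 rose and 7 did not pass, including Egfl7 (from 100.2 to 224 CPM) and Robo4 (from 24.6 to 59.7 CPM). Of 15 fibroblast markers 6 rose, 1 fell (Postn) and 8 did not pass, with Mfap4 going from 50.2 to 199 CPM and Serpinf1 going from 10.7 to 38.6 CPM. Of 15 ventricular cardiomyocyte markers 10 rose and 5 did not pass (13 rose adjusted over the list alone), including Tcap and Cmya5 (from 61.5 to 217 CPM), and 5 rose without P1 replicate 3 or without P14 replicate 2. The other 3 counts were the same adjusted over the list alone. By camera these 4 lists were higher, with adjusted p = 0.00135 for smooth muscle, 0.0396 for endothelial, 0.0407 for fibroblast and 2.65e-04 for cardiomyocyte markers. In the same order they had an adjusted p = 0.206, 0.247, 0.391 and 0.206 with an estimated correlation. Most of the cardiomyocyte markers, Tcap among them, are also in the mature contractile list or the channel list. The rise of the cardiomyocyte list is therefore not a result separate from theirs. The endothelial call ended without P14 replicate 3 (0.0554), and the fibroblast call without P1 replicate 2, P1 replicate 3, P14 replicate 1 or P14 replicate 3 (camera adjusted p from 0.0526 to 0.0742), while the fibroblast median of 0.43 was −0.03 with totals alone.

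Of 7 epicardial and mesothelial markers 4 fell, 0 rose and 3 did not pass (5 fell adjusted over the list alone), with Aldh1a2, which makes retinoic acid, going from 21.2 to 7.48 CPM. Of 10 neuronal and Schwann markers 5 rose, 2 fell and 3 did not pass, with the same counts adjusted over the list alone, including dopamine beta-hydroxylase (Dbh, from 3.51 to 33.4 CPM), Phox2a (from 17.8 to 48.8 CPM) and Fabp7, which fell from 2.97 to 0.929 CPM; 1 fell when any library but P1 replicate 2 or P14 replicate 1 was left out. A further riser of this list, Cryab, is a heat shock protein abundant in heart muscle (from 1246 to 2188 CPM) that the mature contractile list also holds, and it did not pass without P14 replicate 1 or 2 (edgeR adjusted p = 0.0731 and 0.0655). By camera the epicardial list was lower (adjusted p = 0.0116), with an adjusted p = 0.248 with an estimated correlation and 0.0776 without P14 replicate 2. The neuronal list was called higher (adjusted p = 0.0313), with an adjusted p = 0.206 with an estimated correlation. Of 14 atrial and conduction markers 6 fell, 3 rose and 5 did not pass, with the same counts adjusted over the list alone: Myl4 fell from 493 to 112 CPM and Nppa from 594 to 221 CPM, and Nr2f1 rose from 0.803 to 4.15 CPM (list camera adjusted p = 0.141). Of 6 skeletal muscle markers Tnni2 and Mybpc2 rose and 4 did not pass (camera adjusted p = 0.327), also 2 adjusted over the list alone.

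The remaining 3 marker lists had under 5 tested members and were not given a list test. Of 17 lymphocyte and thymocyte genes 5 were in the table and 4 were tested, of which 3 rose, among them Thy1 (from 17.1 to 41.9 CPM). Of 10 adipocyte genes 2 were tested and both rose: the lipid droplet proteins Plin4 (from 36.4 to 166 CPM) and Cidea (from 30.4 to 103 CPM). Of 10 lung epithelium genes 2 were tested and neither passed. Adjusted over the list alone, the rises were 3, 2 and 0.

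**Figure D4:**
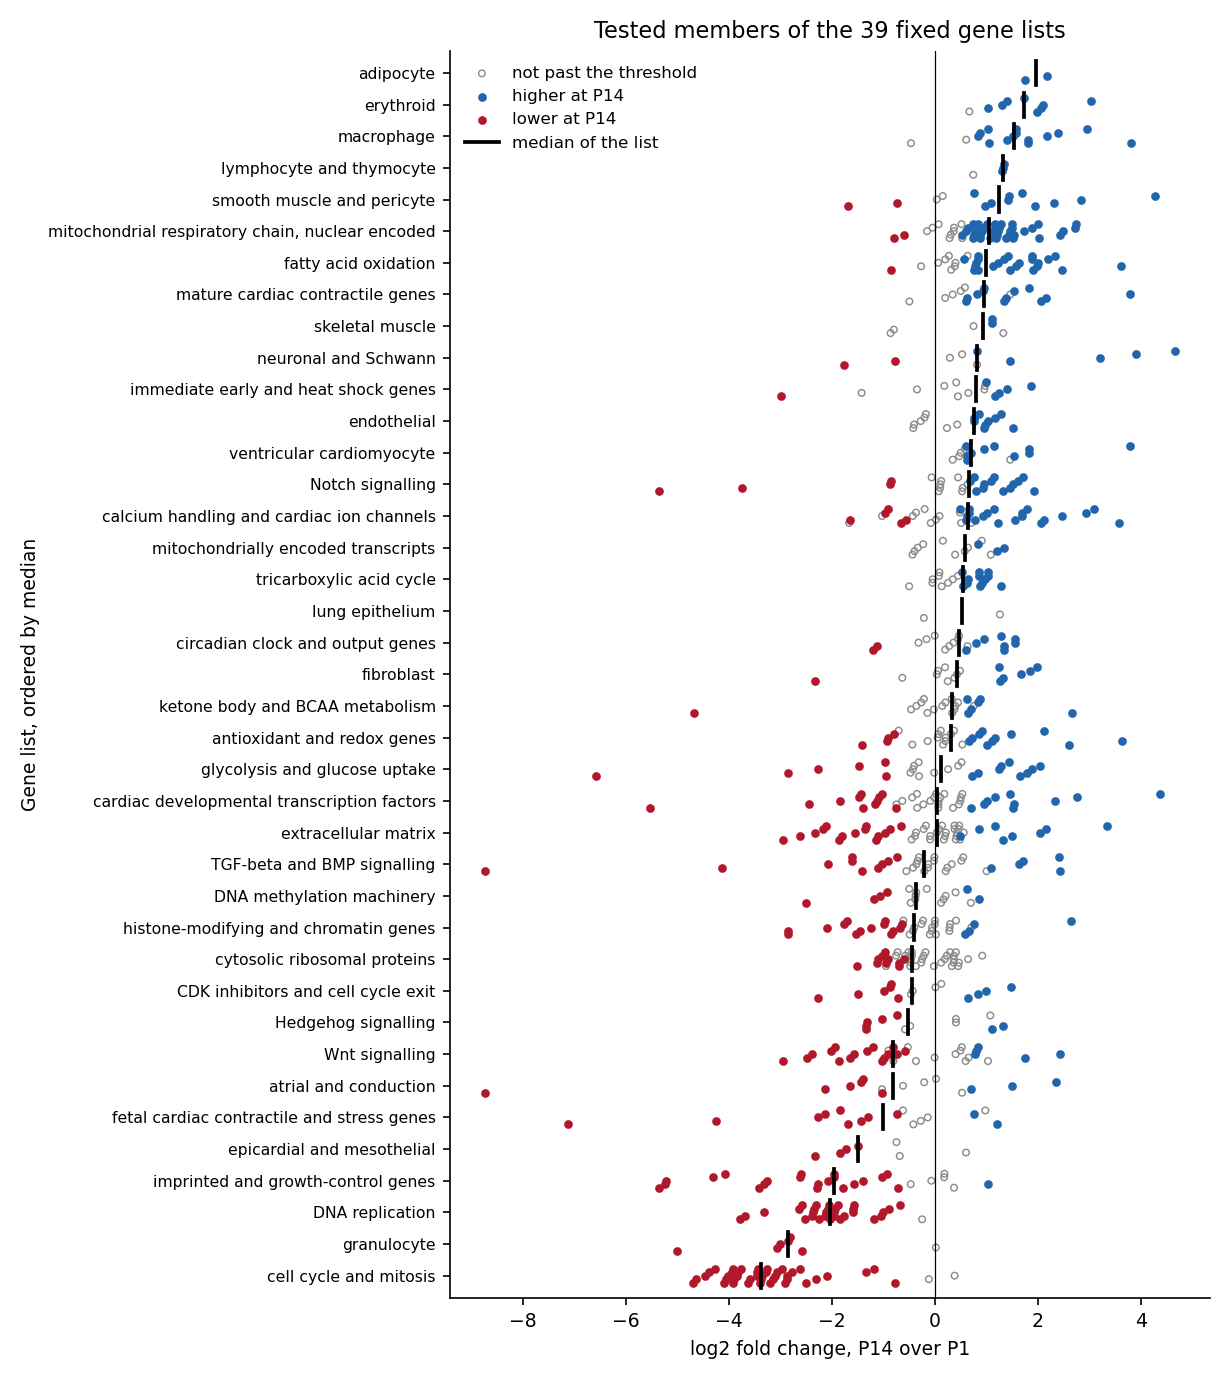
Log2 fold change (P14 over P1, x axis) of each tested member of the 39 gene lists (y axis, ordered by median, with a black bar at the median), where blue members were higher at P14, red members lower, and open circles not past the threshold. The cell cycle and mitosis list has the lowest median, −3.39, and the nuclear respiratory chain list has a median of 1.04.

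Of the 5 largest rises among genes with a mean of at least 10 CPM and no overlap between ages, 3 were of cytoskeletal genes and 2 of noncoding RNAs. The alpha-tubulin Tuba8 (ENSMUSG00000030137; chromosome 6, 121210696 to 121226854) rose from 2.63 ± 0.623 to 245 ± 46.1 CPM, a log2 fold change of 6.49 ± 0.28 (SE; edgeR adjusted p = 3.94e-09). The microtubule-associated protein tau, Mapt (ENSMUSG00000018411; chromosome 11, 104231390 to 104332090), rose from 1.44 ± 0.386 to 91.8 ± 8.17 CPM, and the nonmuscle myosin heavy chain Myh14 (ENSMUSG00000030739; chromosome 7, 44605803 to 44670843) from 1.29 ± 0.251 to 60.8 ± 11.9 CPM. The noncoding Gm15856 (ENSMUSG00000086527; chromosome 6, 121223692 to 121226153), with the largest fold of these, lies antisense within Tuba8, rose from 0.523 ± 0.152 to 84.8 ± 8.04 CPM, and its reads cannot be told from those of Tuba8 without strand. The same holds for Myh14, which overlaps 2310016G11Rik on the opposite strand, and for 2210408F21Rik (from 0.321 to 28.6 CPM), which overlaps Lncpint on the opposite strand. Under the same limits the largest falls, after Tnni1, were of Aldoc, Dlk1, the angiogenesis regulator Vash2 (ENSMUSG00000037568; chromosome 1, 190947646 to 190979296; from 32.6 ± 1.46 to 0.748 ± 0.389 CPM) and the calpain Capn6 (ENSMUSG00000067276; chromosome X, 143802231 to 143827414; from 34.0 ± 2.93 to 0.831 ± 0.202 CPM). The 3 P14 libraries held 1 to 5 counts of Aldoc, 3 to 38 of Dlk1, 4 to 17 of Vash2 and 5 to 15 of Capn6, so the size of these falls rests on few counts.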

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

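The corrections for GC content and length, their combinations and the fit without rRNA-linked genes were chosen only after the results were seen; the other settings were fixed earlier. Against 3115 genes higher and 3149 lower, totals alone gave 1620 higher and 5592 lower, an adjusted p under 0.01 gave 2110 and 2025, and a fold change above 1.5 gave 1763 and 1640, the last 2 because the criterion is stricter. The counts were within 1.5 times of those values in the other settings: 3101 and 3155 with DESeq2 size factors, 2875 and 3454 with upper quartile scaling, 3101 and 3050 in DESeq2, 3251 and 3250 in edgeR's exact test, and 3153 and 3034 with voom. They were 2468 and 2525 with the stricter filter, 3411 and 3964 after the GC correction, and 3455 and 3736 without P1 replicate 2 and with that correction. Leaving out 1 library gave 2387 to 3401 higher and 2269 to 3309 lower. Similar counts were not all the same genes. Of the 3115 and 3149 genes, 2700 and 2968 were called again after the GC correction. With 1 library left out, 2369 to 2933 and 2219 to 2844 were called again. No gene was called in opposite directions in any of these settings. With the replicate block 3561 genes were higher and 3435 lower, 22 lists were called, and the block ended the calls of Bckdha and Hba-a1 and of no other named gene or list; with the block and the GC correction the counts were 3596 and 4082. Of 130 named genes 128 passed, and 102 passed in every setting that tested them. The log2 fold change of Dnmt3a, not past the threshold, was −0.357 with totals alone, −0.158 with the GC correction, −0.142 with that correction and the block, and −0.015 without P1 replicate 2 and with the correction; the cause was not tested. Of the 22 lists called by camera 0 were called with an estimated correlation (lowest adjusted p = 0.206; 6 lists under an unadjusted 0.05), 28 lists passed fry, 17 were called with totals alone, 15 with the stricter filter, 24 with the GC correction and 19 to 23 with 1 library left out. The stricter filter, which tested fewer members, ended the calls of the Notch, histone, endothelial, fibroblast and neuronal lists and left the granulocyte and epicardial lists with 3 members each, too few to test. Among named genes the GC correction ended the calls of Gli1 (log2 fold change 0.732, edgeR adjusted p = 0.0799) and Ier2 (0.51, 0.0758), and with P1 replicate 2 also left out those of Ier2 (0.532, 0.0871), Hba-a1 (1.533, 0.0733), Hba-a2 (1.619, 0.0759) and Vwf (0.297, 0.121); the cause was not tested. The GC correction ended the Notch call and added the ketone, antioxidant and ribosomal lists; with P1 replicate 2 also left out, the fibroblast call ended too. Depth limits genes near 1 CPM, such as Dnmt3b.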

Other observations

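The lists of antigen presentation, tubulin, interferon-inducible and PPAR-alpha target genes were drawn up after values of some of their members were seen, and those members were left out of the counts; the tests of the pool nearer to P14, of the ribosomal RNA shares and of the splits of genes were chosen only after the result was seen. Antigen presentation genes were higher at P14: of 15 tested genes 13 rose and 2 did not pass, with a median log2 fold change of 1.67. The invariant chain Cd74 rose from 3.10 ± 1.33 to 47.8 ± 8.88 CPM, the class II gene H2-Aa from 0.987 ± 0.311 to 11.6 ± 4.15 CPM, and the class I genes H2-K1 and H2-D1 from 17.8 ± 0.82 to 56.4 ± 10.7 CPM and from 31.5 ± 3.46 to 85.2 ± 13.9 CPM (SD, n = 3), while B2m was 113 and 146 CPM and did not pass (edgeR adjusted p = 0.167). With totals alone 10 rose, and without P1 replicate 2 11 rose. This list was higher in camera (adjusted p = 6.5e-07), with an adjusted p = 0.403 with an estimated correlation. Camera p-values of the 4 lists drawn up late are adjusted over these 4 alone. They are descriptive, because the lists followed values already seen in these data. Of 25 interferon-inducible genes 10 rose, 1 fell and 14 did not pass (8 rose and 4 fell with totals alone). Of 18 PPAR-alpha target genes 11 rose, 3 fell and 4 did not pass (6 and 4). Both lists were higher in camera (adjusted p = 0.00452 and 0.0193), each with an adjusted p = 0.414 with an estimated correlation. They are not separate results. The risers Tapbp, H2-D1, H2-K1, Psmb8, Psmb9 and Cd74 are in both the interferon-inducible and antigen presentation lists. The PPAR-alpha list shares members with the fatty acid oxidation list. Counts of these lists were not repeated with the replicate number as a block, which may change which genes pass. Of 16 macrophage markers 14 rose over the same interval, and a larger share of macrophages was not tested as a source of the antigen presentation transcripts.

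Among tubulins and microtubule-associated proteins the isoforms moved apart. Beside the rises of Tuba8 and Mapt, Tuba4a rose from 109 ± 3.95 to 826 ± 205 CPM and Tubb4a from 6.54 ± 1.65 to 14.8 ± 3.11 CPM, while Tubb5 fell from 1317 ± 460.1 to 239.5 ± 59.6 CPM and Tubb2b from 49.3 ± 23.6 to 1.85 ± 0.729 CPM. Stmn1, which destabilises microtubules, fell with a log2 fold change of −3.09 ± 0.38 (SE). Of the 13 members not seen beforehand 2 rose, 6 fell and 5 did not pass, with a median of −0.55, and the list was not called (camera adjusted p = 0.132). With totals alone or upper quartile scaling 8 fell, and 9 fell after the GC correction. No explanation was tested.

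P1 replicate 2 lay apart from the other P1 libraries, at −45.6 on the second principal component against 29.5 and 18.3. Across 14128 genes its deviation from the mean of the other P1 libraries correlated with transcript GC content at rho = −0.684, against 0.554 and 0.416 in the other P1 libraries, whose deviations are taken against it, and 0.164, −0.086 and −0.134 at P14; genes are not independent replicates. A pool of animals further along toward P14 would give a positive slope of this deviation on the age change; over 6264 called genes the slopes were −0.036 and −0.027 with each of the other P1 libraries as reference and 0.029 and 0.022 after the GC and length correction, and since the age change itself correlated with GC content (rho = 0.25, and 0.112 without P1 replicate 2) the sign depends on that trend. This explanation stays open. The cell cycle list, with a median deviation of −0.129 (−0.177 after the correction), lay toward P14. Its member Mki67 (93.2 CPM against 65.9 and 67.7) lay away from it. Of the other called markers chosen in advance, Tnni1 (2190.5 CPM against 4853 and 4265), Myh7, H19, Igf2 and Dnmt1 lay toward P14. Tnni3 (1694 CPM against 2911 and 2001), Myh6 and Cpt1b lay away from it. On the first principal component P1 replicate 2 (−75.5) lay farther from P14 than P1 replicates 1 and 3 (−63.5 and −65.4). A GC-dependent bias in library preparation or sequencing may account for part of the deviation: after the correction its SD fell from 0.622 to 0.459. That fall cannot decide it, because the correction is fitted to the same values on GC content and length and lowers the SD in any library. In P14 replicate 1 the SD fell from 0.512 to 0.461. What remains is open.

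Random sets for P1 replicate 2 were drawn gene by gene, matched on mean expression. Related genes can vary together, so percentiles against such sets may look more extreme than they are. Some interferon-inducible and PPAR-alpha target genes seen beforehand stood high in this same library, such as Iigp1 with a log2 excess of 2.37. Other genes of the same set may vary with them, so the percentiles below are not independent support for either set. In P1 replicate 2 interferon-inducible and PPAR-alpha target genes not seen before had median excesses of 0.217 and 0.236, at percentiles 89.4 and 97.9 of random sets, and 0.501 and 0.36 after the GC correction, above all random sets. The first lies under the 95th percentile of 0.267, the bound set in advance to exclude a rise of the set; it was kept open only after that result was seen, because that bound ignored the GC trend of this library and the corrected value lies past it; neither uncorrected median reached the 0.5 required in advance. In P14 replicate 2, which shares its number, the interferon-inducible genes had a median excess of 0.392 (0.409 after the correction) and the PPAR-alpha target genes one of −0.092 (−0.051), so the interferon excess is not found in P1 replicate 2 alone. The interferon-inducible median was lowest in replicate 3 at both ages (−0.252 at P1 and −0.483 at P14), and replicate 1 lay between (0.028 and 0.103). Whether the interferon excess follows the replicate number was not tested, and both sets stay open.

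Lars2, a mitochondrial leucyl-tRNA synthetase, and the noncoding Gm15564 together took 0.269%, 1.69% and 6.80% of counts in the P1 libraries and 0.57%, 2.73% and 2.13% at P14. Over the 6 libraries their shares had rho = 1 (exact permutation p = 0.00278, adjusted 0.00556 over 2 relations) and r = 0.999 (exact permutation p = 0.00139), and r = 0.996 without the 2 farthest libraries. The Lars2 share and the mitochondrial rRNA share had rho = 0.829 (exact permutation p = 0.0583) and r = 0.706 (exact permutation p = 0.0653). Their transcripts share 17 windows of 36 bases with each other and 0 with annotated rRNA-derived transcripts, so shared sequence may move some reads between them, though where reads fell was not seen. Residual ribosomal RNA in some libraries stays open, because a joint rise of both genes does not show where the reads came from and the relation to mitochondrial rRNA missed the threshold; the first reading of that test as favourable was made stricter after the result was seen, and no biological explanation was tested.

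The 6 libraries can be split 3 against 3 in 10 ways, so the share of splits as large as the real one is never under 0.1. The real split gave 3115 genes higher, 3149 lower and 22 lists, while the highest of the other splits gave 0 genes in edgeR in either direction (30 to 726 genes at an unadjusted p under 0.05, against 7317 in the real split) and 16 lists; 1 split, the real one, reached each of the 3 values. Of the other splits that also part the 3 numbered pairs, the ones that exchange replicate 3, 2 or 1 between the ages gave 16, 12 and 11 lists and 0 genes. The other splits had 6 to 16 lists called by camera with a preset correlation and 0 genes called by edgeR. Each of them puts libraries of both ages in each group. The age change therefore widens the spread within groups, and part of it remains between them. Their counts of genes and lists are thus not those that chance alone would give.

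Of the mitochondrial coding genes, mt-Co1 had 40.3% and mt-Nd4 37.4% unique windows of 36 bases at a mean of 20805 and 10664 CPM; the bound set beforehand for mt-Co1, over 50%, was not met.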
